A study of Mus musculus with 24 samples.

How the data were processed

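Lung RNA of male mice aged 8 weeks was hybridised to Affymetrix Mouse 430A arrays, which measure most genes with one or more probe sets, each a group of short oligonucleotides against the 3' end of a transcript. The 24 arrays came from 12 kinds of mice with 2 arrays each: the inbred progenitors C57BL/6J (B6) and C3H/HeJ (C3), their F1 hybrid, and 9 recombinant inbred (RI) strains of the BXH set, each of which was inbred from that cross and is fixed at most loci for the allele of one progenitor. Groups and replicate numbers were taken from the sample labels. The labels give a number of 1 for each sample but do not say that both arrays of a strain came from separate animals, so all p-values measure only the spread between these samples, which may be technical.

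Per the labels' protocols, total RNA was extracted with Trizol, copied from a T7-oligo(dT) primer, amplified to biotin-labelled cRNA and fragmented before hybridisation. The deposited values are one linear intensity (signal) per probe set and array, and the authors' deposited table holds 22690 probe sets. The software behind the signals and the scaling between arrays are not given in the sources used here. The mean signal after trimming 2 percent of values from each end lay between 500.11 and 500.13 on every array. The array medians lay between 239 and 269.6, a range of 0.17 on the log2 scale. The deposited signals therefore carry a common scaling, and since the range of medians was below the limit of 0.3 set for it, no further normalization was applied. Signals were analysed as log2(signal + 16), so a log2 difference understates the change of dim genes. No background was subtracted here, and whether the deposited signals already had it subtracted is not given. The lowest deposited signal was 0. The number of arrays limits the precision.

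Probe sets were named through the platform annotation. Of the 22690 probe sets, 20380 had one gene symbol, 691 had several and 1555 had none, and 64 were controls. Entrez identifiers of 20351 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for gene order, because the array files name no genome build. Each gene was represented by its probe set with the highest mean over all 24 arrays, and it was tested if that mean was among the top 60 percent of all probe sets, which corresponds to a signal of 169. This left 8280 genes.

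All comparisons came from one linear model with the 12 strains as groups, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), which left 12 residual degrees of freedom. The contrasts were C3 minus B6, F1 minus the mean of both progenitors on the log2 scale (midparent), and each RI strain minus the mean of the other 8 RI strains. Moderated F tests asked whether genes differed between all 12 strains and between the 9 RI strains. A gene passed with an adjusted p (Benjamini-Hochberg, within each contrast) below 0.05. The words rose, fell, higher and lower for a single gene refer to genes that passed, unless a p is given.

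For 75 genes that differed between the progenitors by a log2 value of at least 1, the position of each RI strain was (RI mean minus B6)/(C3 minus B6), nearer C3 above 0.5 and outside the progenitors below -0.5 or above 1.5. For neighbouring genes, the strain means of the 9 RI strains were correlated between consecutive called genes with at most 50 annotated genes between them, and the mean was compared with 10000 permutations of genes over positions. Gene lists for cell types, tissues and pathways were fixed in advance, and 37 of them had at least 4 tested members. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a contrast. Counts of members that passed are given over all genes and adjusted over the list alone. The mean of each list on each array was also tested with a permutation F over the strains (100000 permutations), a test chosen after seeing the data.

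The samples, tests, gene lists, most alternatives and the rule for the named genes were fixed before the data were examined. The rule took the 10 largest and 10 lowest differences of C3 minus B6 with non-overlapping arrays, up to 5 of each sign for F1, the 10 genes with the widest range among RI strains, 8 of each sign for BXH2, the largest and the lowest for each other RI strain, up to 4 members of smallest p for each list described, and Nnt, H2-Ea, Tlr4, Irf8, Sod3 and Glo1. Alternatives were quantile normalization, median centring, offsets of 1 and 64, no filter, the top 40 percent, every probe set, the mean of probe sets, no mean-variance trend, the replicate number as a block, fits on only the arrays compared, and leaving out each array. Which lists are described beyond the myeloid list was chosen after their results were seen. Fits without both BXH4 arrays and with the skeletal muscle list mean as a covariate were added after seeing the data.

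The code was tested on simulated data in which 200 of 8280 genes were changed. For C3 minus B6 it recovered 21.6%, 82.8% and 98.4% of genes changed by log2 values of 0.5, 1 and 2. For F1 minus midparent it recovered 23.9%, 92.4% and 98.7%, and for BXH4 minus the other RI strains 47.6%, 96.1% and 100%. False calls numbered 5, 8 and 4. With alleles of log2 size 1 spread over the RI strains, the F tests over 12 and over 9 strains recovered 90.5% and 88.5%, and with no changed gene each of 4 simulated tests made 0 calls. Simulated values were drawn independently for each gene and array. They lack the deviations that genes share on real arrays, so these rates need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.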

Results

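Lung gene expression was measured on 24 arrays, 2 for each of 9 BXH RI strains, the progenitors B6 and C3 and their F1 hybrid. The series title gives its purpose as a comparison of expression in the RI strains, the progenitors and the hybrid. The correlation over tested genes lay between 0.949 and 0.975 for both arrays of a strain and between 0.909 and 0.969 for arrays of different strains, and 16 of the 24 arrays had their closest partner in their own strain. These correlations are across genes, which are not independent replicates. Over the arrays the Y-linked genes Eif2s3y, Kdm5d and Uty had signals of 277.9 to 936.6, 162.8 to 446.8 and 187.6 to 443.7, and Xist, which is transcribed from the inactive X chromosome, 148.5 to 396.7.

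C3 lungs differed from B6 lungs most in single genes of varied function. Cap1, an actin regulator that binds adenylyl cyclase, rose from a signal of 319 ± 46.7 in B6 to 3422 ± 27.6 in C3 (SD, n = 2 each), a log2 difference of 3.37 (SE 0.18). Rpgrip1, a protein of the photoreceptor connecting cilium, fell from 1469.8 ± 109.5 to 62.8 ± 29.2 (log2 -4.29, SE 0.32). The class I histocompatibility genes H2-D1 and H2-K1, which present peptides to T cells, were lower in C3 by -3.07 and -2.51, with H2-D1 at 8810.4 ± 19.4 in B6 and 1035 ± 71.1 in C3. Gbp2b, an interferon-induced GTPase, was higher by 2.55, and Alad, an enzyme of haem synthesis, by 1.98.

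Among 8280 genes, limma called 62 genes higher and 76 lower in C3 than in B6. In all, 773 genes had an unadjusted p below 0.05 where 414 were due by chance. The other large increases were in Tmem87a, a Golgi membrane protein (2.76), the membrane-bending adaptor Baiap2l1 (2.53), Jchain, which joins polymeric antibodies (2.49), the kinase family member Nme7 (1.91), Gpnmb, a glycoprotein of macrophages and melanocytes (1.90), the haem-binding Hebp1 (1.85) and the NMDA receptor subunit Grin2c (1.84). The other large decreases were in Trim34a, of an antiviral gene family (-2.64), Smim10l1 (-1.89), the purine-degrading enzyme Xdh (-1.87), the vitamin K-dependent carboxylase Ggcx (-1.82), the interferon-induced Ifi209 (-1.80) and Sspn, of the dystrophin complex (-1.68). Nnt, a mitochondrial transhydrogenase in which C57BL/6J carries a known deletion, was higher in C3 by 0.95 (SE 0.14, adjusted p = 6.13e-04), and the detoxifying enzyme Glo1 by 1.15 (SE 0.14, adjusted p = 7.17e-05). Irf8 (0.42, adjusted p = 0.521), the extracellular superoxide dismutase Sod3 (0.04, adjusted p = 0.988) and Tlr4, in which C3H/HeJ carries a known missense mutation (-0.16, adjusted p = 0.941), did not pass.

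Pdxdc1 passed at -2.81, but its probe sets went opposite ways. The median of its 2 other probe sets was 1.32, although 1 of them was also lower in C3 (limma's unadjusted p below 0.05). The tested probe set is that with the highest mean. It changed when any single array of B6, BXH7, BXH8, BXH9, BXH10 or BXH14 was left out. Another probe set then gave up to 3.70, so the direction of Pdxdc1 is not settled. Of the called genes with further probe sets, 6 of 27 lower genes and 2 of 26 higher genes had a median of the opposite sign in these. The other probe set of Smim10l1 gave -0.08, while those of H2-D1 and H2-K1 gave medians of -2.31 and -1.53 and that of Cap1 gave 4.16. The tested probe sets of H2-D1 and H2-K1 are of a type that can also bind related transcripts.

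Of 13 alveolar macrophage genes, Krt79 (1.70) and Ccl6 (1.00), a chemokine, rose in C3 against B6, 6 rose when adjusted over the list alone (Ctsk 0.87 and Car4 0.41 among them), and the camera call (adjusted p = 3.74e-06) was lost at adjusted p = 0.0664 with an estimated correlation. Of 10 class I antigen presentation genes, H2-K1, H2-D1 and H2-M3 (-0.91) fell, and 5 fell adjusted over the list alone, Tap1 (-0.54) included (adjusted p = 0.325 with an estimated correlation). Of 15 circadian clock genes, the repressors Nr1d2 (1.53), Bhlhe40 (1.11) and Nr1d1 (1.68) and the output factor Dbp (1.10) rose, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.439 with an estimated correlation). Of 20 interferon response genes 0 passed, and 1, Gbp2 (-0.76), fell adjusted over the list alone (median -0.31, adjusted p = 0.439 with an estimated correlation). Skeletal muscle genes passed in 0 of 11 cases (median -1.98, adjusted p = 0.569 with an estimated correlation), with per-array means of 10.50 and 10.46 in B6 but 6.80 and 10.35 in C3. Of 6 squamous epithelium genes 0 passed, and 2 fell adjusted over the list alone (median -3.05, adjusted p = 0.439 with an estimated correlation). Camera called 8 of 37 lists, of which 0 were called with an estimated correlation.

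The counts of C3 minus B6 depended on single arrays. They were 35 higher and 43 lower without B6 replicate 1, 41 and 35 without B6 replicate 2, and 34 and 41 without C3 replicate 2. The fit on only the B6 and C3 arrays gave 32 and 39, the fit on only the 6 arrays of B6, C3 and F1 gave 39 each way, and 40 and 41 were higher with the top 40 percent of probe sets and with the muscle covariate. Leaving out 1 array ended the calls of Hebp1 and Nr1d1 and H2-M3 (B6 replicate 1 or C3 replicate 1), Jchain (B6 replicate 2 or C3 replicate 2), Dbp (B6 replicate 2 or C3 replicate 1), Ccl6 (either B6 array or C3 replicate 2), Grin2c (any of these 4) and Xdh (C3 replicate 2), with highest adjusted p from 0.0520 for Xdh to 0.445 for Jchain. Jchain stood at 3.70 and 1.27 without B6 replicates 1 and 2, whose mean signal was 227 ± 236 (SD, n = 2). Calls also ended for Grin2c with an offset of 1, no filter or the covariate (adjusted p up to 0.0972), for Jchain with no filter, the covariate or only 4 arrays (up to 0.179; with the covariate Grin2c stood at 1.77, SE 0.48 in place of 0.43, and Jchain at 2.44, SE 0.64 in place of 0.58), and for Bhlhe40, Dbp, Nr1d1 and H2-M3 with only 4 arrays (up to 0.0854).

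**Figure D1:**
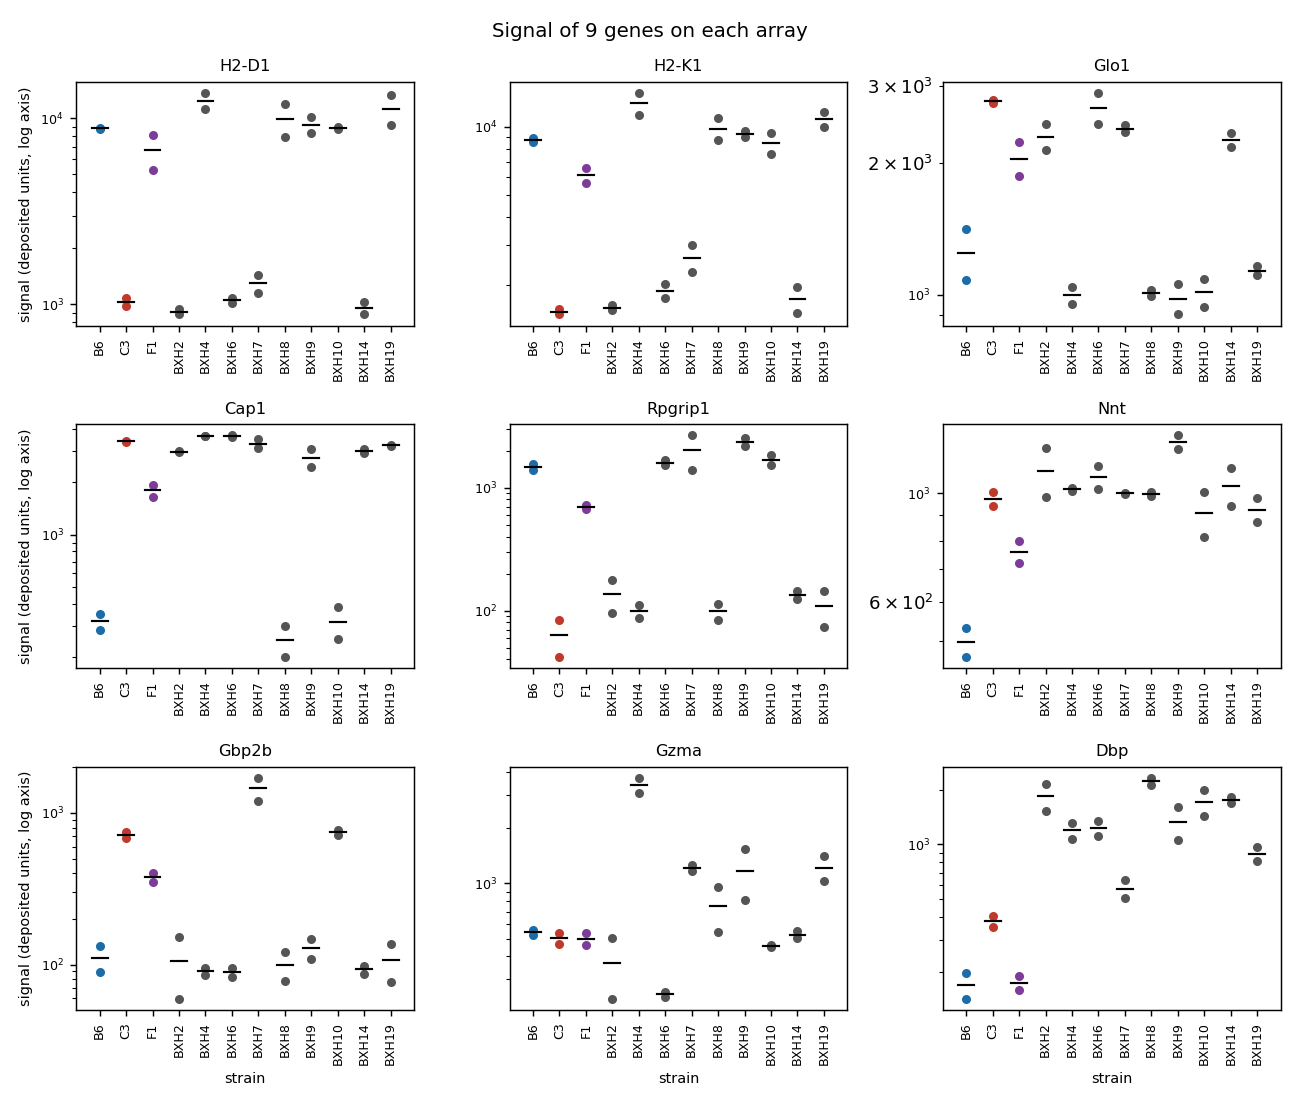
Deposited signal (log axis) of 9 genes on each of 24 arrays, by strain; points are arrays and bars the mean of both arrays of a strain. H2-D1, H2-K1 and Glo1 group BXH2, BXH6, BXH7 and BXH14 with C3, while Cap1 lies at 249.6 in BXH8 and 318 in BXH10, near the 319 of B6.

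The median position of the F1 hybrid lay near the middle of its progenitors on the log2 scale. For H2-D1 the F1 signal was 6711 ± 2029 (SD, n = 2), above the midparent by a log2 value of 1.11 (SE 0.18), and Baiap2l1 was above it by 0.87 (SE 0.14), each with limma's adjusted p = 0.0379. Lower genes numbered 0, while 676 genes had an unadjusted p below 0.05 where 414 were due by chance. The midparent is a mean of log2 values, so for genes that differ widely it lies below the mean of both signals. Across the 75 genes with a progenitor difference of at least 1, the median F1 position was 0.48, and 50 lay between 0.25 and 0.75. This median pools genes higher and lower in C3, and shifts toward the higher progenitor in both would cancel in it. Of genes higher in C3, Cap1 (0.72), Tmem87a (0.81) and Baiap2l1 (0.84) lay nearer C3, but Nme7 (0.34) and Jchain (0.16) nearer B6. Of genes lower in C3, H2-D1 (0.14), H2-K1 (0.21) and Rpgrip1 (0.25) lay nearer B6, but Ang (0.66) and Akr1e1 (0.63) nearer C3.

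Of 21 lipid metabolism genes 0 passed over all genes in F1, and 3 rose adjusted over the list alone: Pdk4, which restrains glucose oxidation (1.58), the thioesterase Acot1 (0.81) and the fatty acid carrier Fabp4 (1.65). This list kept its camera call with an estimated correlation (adjusted p = 0.0387), alone among 18 lists called in F1. F1 had the highest strain mean of this list, but its arrays differed, with 10.84 on replicate 1 and 10.50 on replicate 2. The list means were 10.47 and 10.41 in B6, 10.29 and 10.19 in C3, and 10.59 and 10.56 in BXH2. The adipose list mean was also higher on F1 replicate 1 than on replicate 2 (10.27 and 9.20). Of 18 cell cycle genes 0 passed over all genes and 12 fell adjusted over the list alone, among them Top2a (-0.83), Ccnb2 (-1.02), Ccna2 (-0.75) and Birc5 (-0.99), and the call was lost at adjusted p = 0.154 with an estimated correlation. The cell cycle list means were 7.89 and 8.25 on the F1 arrays, 8.87 and 8.74 in B6, and 8.23 and 9.10 in C3. On the RI arrays they ran from 7.94 to 8.67. The highest strain mean was that of B6 and the lowest that of BXH9, so the fall in F1 is relative to high progenitor arrays. The count of F1 genes was 0 with no filter, with no trend, with only the 6 arrays of B6, C3 and F1 and without B6 replicate 1, C3 replicate 2 or either BXH6 array, 1 with quantile normalization, without both BXH4 arrays and without B6 replicate 2, F1 replicate 1, or any single array of BXH2 or BXH4, 10 higher and 2 lower with every probe set, 5 higher and 9 lower without C3 replicate 1, and 5 without F1 replicate 2, where neither H2-D1 nor Baiap2l1 was among them. H2-D1 reached an adjusted p of 0.309 and Baiap2l1 of 0.137 with 1 array left out. Pdk4 passed over all genes with every probe set (adjusted p = 0.0493), but its difference ranged from 0.78 to 2.38 with 1 array left out.

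Across all strains, 866 genes (10.5%) differed between the 12 strains and 772 (9.32%) between the 9 RI strains, and 701 passed both. Among RI strain means the range was wide in muscle genes: Myl1, a fast muscle light chain (log2 range 5.92, highest in BXH8), fast troponin T Tnnt3 (4.90, highest in BXH9), the developmental myosin Myh8 (4.44, highest in BXH2) and Myl3, of slow and cardiac muscle (3.82, highest in BXH2). It was also wide in Rpgrip1 (4.38), Trim34a (4.13), Cap1 (3.81), Gbp2b (3.80), H2-D1 (3.74) and Gzma, a granzyme of natural killer (NK) and cytotoxic T cells (3.69, highest in BXH4). Signals fell to 29.2 for Myh8 in BXH6 and 51.4 for Trim34a in BXH8, so these ranges and their order depend on the offset: with offsets of 1 and 64 Myh8 had 5.29 and 3.45, Trim34a 4.55 and 3.35, and Rpgrip1 4.58 and 3.90. Of the 138 genes that differed between the progenitors, 114 passed between the RI strains, where 12.9 are due for independent lists; both tests share 1 estimate of the spread.

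By list means per array, 14 of 37 lists differed between strains in the permutation test after adjustment. These include a list of known strain differences, which had the largest F (39.98) and whose outcome was due in advance. That list and the class I antigen presentation genes reached the smallest p that the permutations can give, 1e-05 (adjusted p = 1.85e-04 each). Class I genes were highest in BXH4 and lowest in BXH14. Clock genes were highest in BXH10 and lowest in B6 (adjusted permutation p = 3.7e-04), and NK cell genes were highest in BXH4 and lowest in BXH6 (adjusted permutation p = 0.00236). Class II genes, highest in BXH4 (adjusted permutation p = 6.47e-04), alveolar macrophage genes, highest in BXH19 (0.00243), and interferon response genes, highest in BXH4 (0.00404), passed as well. Skeletal muscle genes had a permutation p of 0.0490 and an adjusted p of 0.0887. Squamous epithelium genes had a permutation p of 0.148.

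Genes that separate B6 and C3 split the RI strains in different ways. H2-D1, H2-K1 and Glo1 were nearer C3 in the same 4 strains, BXH2, BXH6, BXH7 and BXH14. Cap1 was nearer C3 in 7 of 9 strains, Rpgrip1 in 5, Tmem87a in 3 and Gbp2b in 2 (BXH7 and BXH10). Nnt was above B6 in 9 of 9 RI strains, from 909 in BXH10 to 1269 in BXH9 against 498 in B6 and 973 in C3. Over 75 genes the median share of RI strains nearer C3 was 44.4%, and of 675 positions 12.7% lay between 0.3 and 0.7 and 5.93% outside the progenitors. Genes with 0 and with 9 strains nearer C3 numbered 6 each where a binomial gives 0.146. The former were Armcx4, the Y-linked initiation factor Eif2s3y, the growth factor Hbegf, Ppp1r21, Reep6 and the glutamine carrier Slc1a5, and the latter Jchain, Wdfy1 and the clock genes Bhlhe40, Dbp, Nr1d1 and Nr1d2; these were named after their values were seen. Nearer C3 includes values beyond C3: Dbp lay outside the progenitors, past C3, in 9 RI strains and Nr1d2 in 5. Genes are linked, and clock genes can vary together. The 75 genes were also chosen on the same B6 and C3 arrays that set the scale of positions. A deviation of a progenitor's arrays alone can therefore place all RI strains on the same side. The binomial is thus only a reference and no p was computed.

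Neighbouring genes shared their pattern across the RI strains on average, with 4 of 27 pairs below 0. Rnase4 and Rpgrip1 correlated at 0.97 over 9 strain means signed by the progenitor difference, Alpl and Pink1 at 0.98, and Lst1 and H2-D1 at 0.76, whereas Mfap5 and Clec4n correlated at -0.62, Ch25h and Ankrd1 at -0.59, Nnt and 4833420G17Rik at -0.54, and Adh1 and Gbp2b at -0.12; these pairs were chosen after their values were seen and not tested singly. Over 27 pairs the mean correlation was 0.578, against 0.0047 for pairs on different chromosomes, with the smallest permutation p possible (1e-04, one family of 1 test). It was 0.305 without C3 replicate 1 (permutation p = 0.0018).

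BXH2 carries a known point mutation in Irf8, a transcription factor of myeloid cells. Its lungs had less H2-D1 (-2.25), H2-K1 (-1.79), Baiap2l1 (-1.84), Ggcx (-1.76), Rpgrip1 (-1.71), Ilf2, an RNA-binding protein (-1.95), and Grin2c (-1.47) than the mean of the other RI strains. They had more Trim34a (2.00), the neutrophil granule protein Ltf (1.89), creatine kinase Ckm (1.63), Smr2 (1.44), the leukocyte gene Lst1 (1.43), the immediate early factor Egr1 (1.32), the oxygen carrier Mb (1.31), the red cell anion exchanger Slc4a1 (1.31) and Glo1 (0.69). Several of these followed a progenitor level that other RI strains shared. Trim34a had a signal of 876 in BXH2 and 992 to 1084 in BXH7, BXH14 and BXH19, near the 894 of B6. Baiap2l1 had 680 in BXH2, 652 in BXH7 and 616 in BXH8, near the 637 of B6. H2-D1, H2-K1 and Glo1 were also nearer C3 in BXH6, BXH7 and BXH14. Ggcx was nearer C3 only in BXH2. Whether any difference stems from the Irf8 mutation was not tested. Irf8 differed by -0.46 (SE 0.15, adjusted p = 0.170) and 0 of 16 genes of the Irf8-linked myeloid list passed, while 3 fell adjusted over the list alone: Cx3cr1 (-0.69), Irf8 and Ctss (-0.40). Nnt (0.11), Sod3 (-0.10) and Tlr4 (0.01) did not pass, and Pdxdc1 (-1.39) has the unsettled probe sets described above.

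Limma called 48 genes higher and 49 lower in BXH2, with 939 at an unadjusted p below 0.05. Of 13 neutrophil granule genes Ltf and Mpo (1.03) rose and 4 rose adjusted over the list alone (adjusted p = 0.235 with an estimated correlation). Of 16 immediate early genes Egr1 and Nr4a1 (1.02) rose and 6 rose adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). Of 11 skeletal muscle genes 4 rose, Ckm, Pygm (1.05), Eno3 (0.99) and Atp2a1 (1.28), and 11 rose adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). With the muscle list as a covariate 35 genes were called in place of 97, and 9 named genes no longer passed (adjusted p from 0.0591 to 0.446). Of these, Trim34a stood at 1.75 (SE 0.39, before 0.33), Ltf at 1.58 (0.41, before 0.35), Ilf2 at -1.80 (0.45, before 0.37), Grin2c at -1.38 (0.40, before 0.33) and Slc4a1 at 1.10 (0.35, before 0.30), smaller differences with a wider spread. Mb stood at 0.95 (SE 0.22 with and without), and the list members Pygm at 0.73, Eno3 at 0.43 and Atp2a1 at 0.56, whose own values enter the covariate.

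The BXH2 counts were 9 higher and 28 lower without its replicate 1, and 14 and 29 without its replicate 2. Leaving out BXH2 replicate 1 ended the calls of Trim34a, Ltf, Lst1, Mb, Mpo, Slc4a1, Ilf2 and all 4 muscle genes, and leaving out BXH2 replicate 2 those of Ltf, Smr2, Egr1, Nr4a1, Slc4a1, Ilf2, Rpgrip1, Grin2c, Glo1 and the same 4, with a highest adjusted p per gene from 0.0637 for Smr2 to 0.618 for Grin2c. Without BXH2 replicates 1 and 2 Grin2c stood at -2.55 and -0.39, and Egr1 at 0.69 without the latter. Slc4a1 was also lost without BXH8 replicate 1, and Ckm without any of 13 other arrays (both of BXH7, BXH8, BXH9, BXH19, B6 and F1, and BXH6 replicate 2). Eno3 was lost without BXH6 replicate 2, BXH7 replicate 1, BXH8 replicate 2 or BXH9 replicate 2 as well, with no filter and without both BXH4 arrays (0.0535 and 0.0658), and Atp2a1, at an adjusted p of 0.0497, without any of 15 other arrays (both of BXH6, BXH7, BXH8, BXH19, B6 and F1, and replicate 2 of BXH4, BXH10 and BXH14). Atp2a1 ended also with quantile normalization, median centring, an offset of 1, no filter, every probe set, no trend and without both BXH4 arrays (0.0510 to 0.0793). Ckm ended with quantile normalization, median centring, no filter and no trend, and Slc4a1 and Grin2c with no filter and without both BXH4 arrays, the former with an offset of 1 as well (adjusted p from 0.0505 to 0.0758).

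BXH4 lungs differed most from the other RI strains, with cytotoxic lymphocyte genes higher. All 8 NK cell genes rose, led by the chemokine Ccl5 (2.55, SE 0.17), the granzyme Gzma (2.40, SE 0.23), the granule protein Nkg7 (1.69) and perforin Prf1 (1.12), and the list kept its call with an estimated correlation (adjusted p = 0.0424). Of 20 interferon response genes 9 rose, among them the regulator Irf7 (1.43) and the RNA sensor Oas2 (1.18), and 15 rose adjusted over the list alone (adjusted p = 0.0943 with an estimated correlation). Of 10 class I genes 5 rose, H2-D1 (1.95), H2-K1 (1.56), Tap1 (0.92) and H2-M3 (0.90) among them, and 9 adjusted over the list alone (adjusted p = 0.0717 with an estimated correlation). The signal of H2-D1 was 12409 ± 1673 (SD, n = 2) in BXH4, 8842 to 11225 in BXH8, BXH9, BXH10 and BXH19, and 912 to 1295 in the 4 strains nearer C3, which also enter the mean it is set against. Of 8 class II genes 3 rose, the regulator Ciita (0.87), H2-DMa (0.38) and H2-Ab1 (0.53), and 6 adjusted over the list alone (adjusted p = 0.190 with an estimated correlation).

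In the same lungs 2 of 8 mucous genes rose, the airway mucin Muc5b (1.52) and the antibody transporter Pigr (0.92), and 7 adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). The heat shock genes Hsph1 (1.34), Hspa1a (1.87) and Hspa1b (2.17) rose, 3 of 13, and 7 adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). Of 25 oxidative phosphorylation genes 5 fell, Cox5a (-0.48) and Cox4i1 (-0.48) among them, and 12 adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). Among genes that passed, the chitinase-like Chil4 showed the largest rise (2.70; signal 1180 ± 324 in BXH4 but 2373 ± 3080 in BXH6, SD, n = 2 each) and Myl3 the largest fall (-2.17). The skeletal muscle list means were 9.34 and 6.60 on the BXH4 arrays. Cardiac muscle and adipose list means were lowest in BXH4 of all strains, where 4 of 14 and 2 of 6 members fell (adjusted p = 0.437 each with an estimated correlation; adjusted permutation p between strains 0.112 and 0.0887).

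Limma called 291 genes higher and 341 lower in BXH4, with 1916 at an unadjusted p below 0.05. Called genes with an absolute log2 difference of at least 1 numbered 58 in BXH4, 45 in BXH9 and 35 in BXH8. The median correlation of BXH4 replicate 2 with arrays of other strains was 0.924, the lowest of the 24 arrays, where the other values were 0.939 and above. The counts were 92 and 151 without BXH4 replicate 1, 52 and 82 without BXH4 replicate 2, and 187 higher with the muscle covariate. Without either array Muc5b, Pigr, Hsph1, Hspa1a, Hspa1b, the oxidative phosphorylation genes Cycs (-0.43) and Uqcrfs1 (-0.42), and all 3 class II genes no longer passed (highest adjusted p from 0.0733 to 0.378). The interferon response genes Oasl2 and Stat2 were lost without BXH4 replicate 1 (0.0812 and 0.0957). Cox5a, Cox4i1 and Myl3 were lost without BXH4 replicate 2 (adjusted p up to 0.0786, 0.341 and 0.631), Cox4i1 at -0.30 and Myl3 at -0.63, and without BXH4 replicate 1 Myl3 stood at -3.72. With the muscle covariate Ciita (0.80), H2-DMa (0.38), H2-Ab1 (0.46) and Cycs (-0.38) did not pass (0.0618 to 0.0942), with SE moving by at most 0.01. Ciita was lost with no filter (0.0504) and H2-Ab1 with no filter, median centring, no trend (0.0561 to 0.0673) and without any of 12 further arrays (both of BXH6, BXH7, BXH19 and B6, and replicate 1 of BXH2, BXH9, BXH10 and BXH14). Calls also ended for Myl3 with the mean of probe sets (0.0537), and Chil4 with no filter, with no trend and without any 1 of 17 arrays (both of BXH4, BXH8, BXH9, BXH14, BXH19, B6 and F1, BXH2 replicate 1, BXH7 replicate 2 and BXH10 replicate 1; adjusted p up to 0.293).

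BXH7 lungs stood out from the other RI strains in clock genes. Of 15 clock genes 8 fell, among them Dbp (-1.33), the related factor Hlf (-0.89), the repressor Per3 (-1.02) and Tef (-0.71), while 1, the activator Arntl (1.28), rose, and 12 fell and 2 rose adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.0195). The clock list mean, 9.18 on both BXH7 arrays, lay within the 8.87 to 9.21 of B6, C3 and F1. On the other RI arrays it was 9.46 to 10.13. The Dbp signal of BXH7, 571, was still above the 169 of B6 and the 378 of C3. The labels do not give the hour of collection. Gbp2b rose by 3.32 and Baiap2l1 fell by 1.91 on the log2 scale. In BXH6, Rpgrip1 rose by 2.18 and Marco, a scavenger receptor of macrophages, fell to a signal of 20.8 ± 4.6 (SD, n = 2), within the 6.65 to 31.2 of B6 on the probe sets of H2-Ea, in which B6 carries a known deletion, so the size of the fall (2.86, or 3.52 and 1.92 with offsets of 1 and 64) depends on the offset. In BXH8 and BXH9, Myl1 rose by 3.77 and 3.61, while Cap1 fell by 3.21 in BXH8 and the transcription factor Zbtb16 by 2.19 in BXH9. Of 11 skeletal muscle genes 5 rose in BXH9, Pvalb (2.04) and Atp2a1 (1.86) among them, and 11 adjusted over the list alone (adjusted p = 0.281 with an estimated correlation).

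The counts of higher and lower genes by limma were 92 and 69 in BXH6, 52 and 55 in BXH7, 65 and 50 in BXH8, and 103 and 69 in BXH9. Without the strain's replicate 1 the higher and lower genes were 24 and 23 in BXH6, 9 and 12 in BXH7, 5 and 15 in BXH8, and 16 and 7 in BXH9. Without replicate 2 they were 31 and 30, 17 and 17, 24 and 18, and 54 and 27, and with the muscle covariate the totals were 98, 49, 51 and 53. The top 40 percent of probe sets gave 75 in BXH8. BXH9 replicate 1 had the highest ratio of 3' to 5' signal of Actb of the 24 arrays (1.55, next 1.41) and cardiac muscle list means were 11.61 and 10.03 on the BXH9 arrays. In BXH9 median centring gave 95 higher and 45 lower, every probe set 136 and 125, and the mean of probe sets 123 and 111. Myl1 was lost in both strains with the covariate (0.0612 at 1.48, SE 0.34 in place of 0.84, in BXH8, and 0.432 at 0.89, SE 0.36 in place of 0.84, in BXH9), with no filter (0.0560 and 0.0540) and without either array of the strain (up to 0.363 and 0.242), and Atp2a1 with the covariate (0.0537 at 1.00) and without BXH9 replicate 2 (0.147 at 1.19). Eno3 (1.26) and Pygm (0.95), which also rose in BXH9, were lost with the covariate (0.0683 at 0.60, and 0.350 at 0.58) and without either BXH9 array (0.148 and 0.172). Hlf and Tef were lost without BXH7 replicate 1 (adjusted p of 0.0527 and 0.133) and Per3 without BXH7 replicate 2 (0.101). Zbtb16 ended with quantile normalization, median centring, an offset of 64, no filter, no trend, without both BXH4 arrays (adjusted p from 0.0506 to 0.0774) and without any 1 of 16 arrays (both of BXH4, BXH6, BXH7, BXH9, BXH19, B6 and F1, BXH8 replicate 2 and BXH10 replicate 1; up to 0.367).

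In BXH14 lungs antigen presentation genes of both classes were lower. Of 10 class I genes 5 fell, with H2-D1 at -2.18, H2-K1 at -1.67, Tap1 at -1.02 and H2-M3 at -0.85, and of 8 class II genes 4 fell, H2-Eb1 (-1.21), H2-DMa (-0.74), H2-Ab1 (-0.79) and H2-Aa (-0.64). The BXH14 signal of H2-D1, 955, lay near the 912 to 1295 of BXH2, BXH6 and BXH7. Adjusted over the list alone 6 fell in each, and both calls held with an estimated correlation (adjusted p = 0.0330 each). In BXH19 lungs, 2 of 13 alveolar macrophage genes rose, Krt79 (1.29) and Ccl6 (0.92), and 9 rose adjusted over the list alone, a call that held with an estimated correlation (adjusted p = 0.0310). Trim34a rose in BXH14 (2.20) and BXH19 (2.36), and Rpgrip1 fell in BXH19 (-2.05). In BXH10, Gbp2b rose (2.27) and Cap1 fell (-2.85).

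The counts of higher and lower genes were 59 and 63 in BXH10, 43 and 59 in BXH14, and 40 and 61 in BXH19. Median centring gave 46 and 76 in BXH10, whose replicate 2 had the highest ratio of 3' to 5' signal of Gapdh (1.13). Without the strain's replicate 1 they were 22 and 23, 7 and 13, and 8 and 23, and without replicate 2 they were 20 and 41, 39 and 49, and 11 and 21. In BXH19 the top 40 percent gave 38 lower and leaving out both BXH4 arrays 63 higher. H2-DMa, H2-M3, H2-Ab1, H2-Aa and Tap1 no longer passed without BXH14 replicate 1 (adjusted p from 0.0739 to 0.729, H2-Aa at -0.40), nor Ccl6 without either BXH19 array (up to 0.193). Whether an effect differs between 2 RI strains was not tested for any of these genes.

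**Figure D2:**
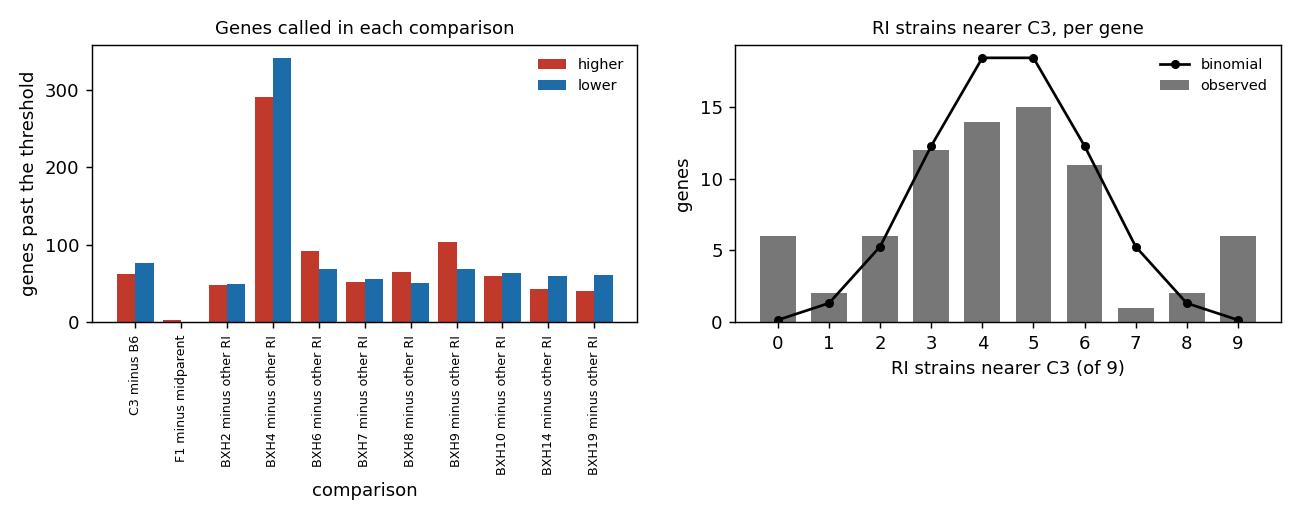
Left, number of genes past the threshold in each comparison, higher and lower; BXH4 has 291 and 341. Right, number of genes (grey bars, 75 in all) by how many of the 9 RI strains lay nearer C3, with the binomial number (black line); 6 genes lie at 0 and 6 at 9.

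**Figure D3:**
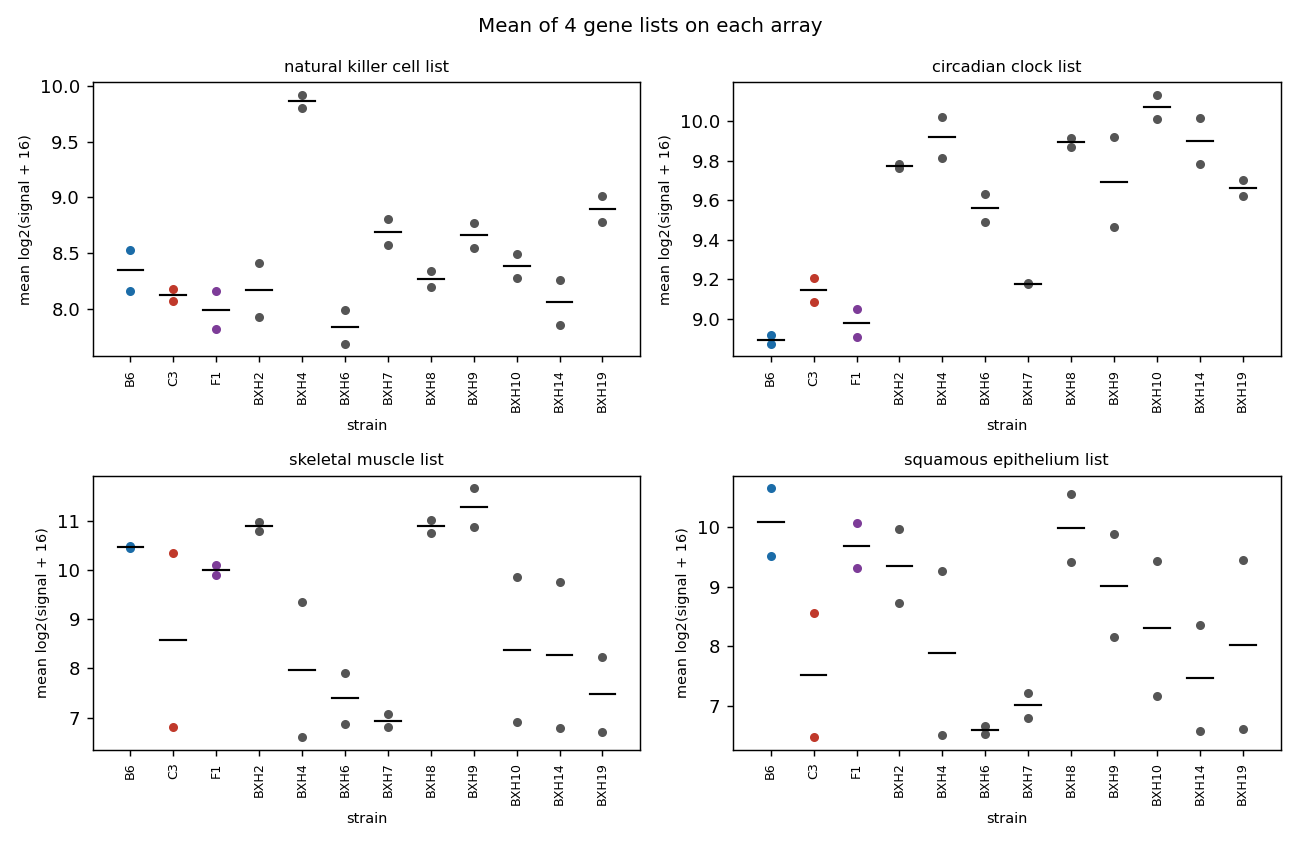
Mean of log2(signal + 16) over the members of 4 gene lists on each of 24 arrays, by strain; points are arrays and bars the mean of both. NK cell genes were highest on the BXH4 arrays (9.92 and 9.80), and skeletal muscle genes lay at 6.80 and 10.35 on the C3 arrays.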

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

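The tests of muscle carried at random, of muscle carried alike within a strain, of pieces of oesophagus, of degraded RNA and of BXH4 against strains that also lost an array were chosen only after the results were seen.

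Probe sets without a single gene symbol, which no comparison of named genes used, also differed between strains. Of 1085 such probe sets above the same filter, 27 (2.49%) passed for C3 minus B6, 11 higher and 16 lower, and 137 (12.6%) passed between the 12 strains.

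The 866 genes that differed between the 12 strains were set against 100 random pairings of the arrays. Only 1 pairing, the real one, gave as many genes, and the highest of the others gave 10. Arrays of a strain thus resembled each other more than randomly paired arrays did. They may also share an animal or handling, so the pairings cannot tell a strain difference from such a shared origin.

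Genes whose signal differed between C3 and B6 may partly reflect a sequence difference under the probes and not a difference in transcript level. If so, the other probe sets of the same genes would show little of the difference. For 27 genes lower in C3 with other probe sets, their median difference in the called direction was 0.37 (bootstrap interval 0.08 to 0.62) against 0.85 for the called lower genes. For 26 genes higher in C3 it was 0.60 (0.26 to 1.09) against 1.01. The interval of the lower genes spans both bounds written beforehand. That of the higher genes lies, narrowly, above the bound set for mismatch but not wholly above the bound set against it, so a partial share stays open, and true allelic difference, which the strains' design names, was not tested separately.

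Strain means of the skeletal muscle list varied, with 11 of 11 members above 0 in BXH9 (adjusted p = 0.281 with an estimated correlation). Muscle carried along at random from lung to lung cannot be told apart from a difference between strains: the permutation p of the list was 0.0490, its error from the number of permutations (0.0477 to 0.0504) spans the bound of 0.05, and the p adjusted over 37 lists was 0.0887. Pieces of oesophagus, which holds striated muscle and squamous epithelium, are a candidate source: the differences of both lists between the arrays of a strain correlated at 0.836 (through the origin over 12 strains, exact one-sided sign-flip p = 0.00903; Pearson's r 0.830, exact p = 0.00952; Spearman's rho 0.797, exact p = 0.00781; 1 relation computed), with the same sign in 9 of 12 strains and 0.819 without C3 and BXH14. Between arrays Acta1 spanned signals of 24.1 to 8772, Myh1 3.5 to 6556, Krtdap 8.7 to 1876 and Krt13 8.3 to 3675; 4 of 11 muscle and 0 of 6 squamous genes exceeded the filter on every array, and 0 were in another list. Muscle carried alike in the lungs of a strain, as by a shared dissection day, cannot be told apart from the strain, because the labels give no day, and the source of strain differences in single muscle genes stays open.

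BXH4 stood apart with 632 called genes (134 without its replicate 2, 243 without its replicate 1) where the next RI strain had 172. Setting these counts from 1 array against the 172 from 2 arrays decides nothing, because every RI strain lost calls without one of its own arrays. Among strains that lost an array in this way, both BXH4 counts lay above the highest of the others, 88, which argues against one divergent array as the whole cause, but replicate 2 also had the lowest median correlation with other strains of all arrays (0.924), so a share from this array stays open. Of the 4 ratios of 3' to 5' signal of Gapdh and Actb in BXH4, 0 lay above the other 22 arrays. This argues only against RNA more degraded than on every other array. Replicate 2 had 0.99 for Gapdh and 1.34 for Actb, against 0.80 and 1.10 on replicate 1. The medians over all arrays were 0.92 and 1.22, so a smaller share from RNA quality stays open. Most BXH4 calls were small: 58 reached an absolute log2 difference of 1, against 45 in BXH9. A difference of the strain itself, or of its lungs at collection, stays open and untested.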

How the results depend on the processing

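The fits without both BXH4 arrays and with the skeletal muscle covariate were chosen only after the results were seen. No detection calls were used here, so the limit set by signal over background was judged only from the filter and the offsets. Of 145 results for named genes, 110 past the threshold, from 121 to 143 kept direction and side of the threshold under each alternative that could be run on all 145; no filter ended 15 calls, no trend 7, and the muscle covariate 20.

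Counts moved by over 1.5 times as follows. F1 genes, 2 in the main setting, were 1 with quantile normalization, 0 with no filter, 12 with every probe set, 0 with no trend, 0 with only 6 arrays and 1 without both BXH4 arrays. C3 minus B6 (62 higher, 76 lower) had 40 higher with the top 40 percent, 41 higher with the muscle covariate, 39 higher and 39 lower with only 6 arrays, and 32 and 39 with only 4, fits with fewer samples. BXH8 (115) had 75 with the top 40 percent, a setting with fewer genes tested. With the muscle covariate BXH2 had 35 (from 97), BXH6 98 (161), BXH7 49 (107), BXH8 51 (115) and BXH9 53 (172). In 1 direction, BXH9 lower genes (69) were 45 with median centring, 125 with every probe set and 111 with the mean of probe sets, BXH19 had 38 lower (61) with the top 40 percent and 63 higher (40) without both BXH4 arrays, and BXH4 187 higher (291) with the covariate. List calls fell from 160 of 407 to 6 with an estimated correlation, by its construction a wider null. For the others the cause was not tested.

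Reversals were in Pdxdc1, whose probe sets go opposite ways, and in values near 0 that never passed. With an offset of 64 or only 4 arrays another Pdxdc1 probe set had the highest mean and was tested. Pdxdc1 in C3 minus B6 (-2.81) was 3.18 with an offset of 64 and 3.63 with only 4 arrays, and -0.06 with the mean of probe sets; in BXH2 (-1.39) it was 1.92 with an offset of 64 and 0.0022 with the mean of probe sets. With the muscle covariate Sod3 was -0.0674 in C3 minus B6 and 0.0245 in BXH2, and Tlr4 -0.0394 in BXH2; for these the cause was not tested.

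Leaving out 1 array gave these ranges, a lone array being assumed to vary like the other strains. C3 minus B6 had 34 to 64 higher and 35 to 78 lower, F1 0 to 14, the F tests 695 to 867 over 12 strains and 592 to 821 over 9, and the RI strains 37 to 113 (BXH2), 134 to 722 (BXH4), 47 to 203 (BXH6), 21 to 145 (BXH7), 20 to 130 (BXH8), 23 to 219 (BXH9), 45 to 145 (BXH10), 20 to 127 (BXH14) and 31 to 117 (BXH19). The share nearer C3 was 33.3% to 44.4%, the neighbour correlation 0.305 to 0.785 and list calls 148 to 168. Pdxdc1 ranged from -3.07 to 3.70 in C3 minus B6 and from -1.46 to 2.23 in BXH2, Sod3 from -0.11 to 0.18 and from -0.26 to 0.0598, Tlr4 from -0.34 to 0.0309 and from -0.0746 to 0.0854, and Nnt in BXH2 from -0.058 to 0.27.

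Same-numbered arrays of different strains did not deviate together as a set: over 66 pairs of strains the correlation of deviations had a median of -0.0037. It lay between -0.30 and 0.34, with 22 above the limit of 0.1 set for it. Single pairs of strains thus shared deviations, in the same or the opposite direction, but the numbers do not pair the samples as a whole. With the replicate block C3 minus B6 had 57 higher and 72 lower and F1 3, Pdk4 passed in F1 (adjusted p = 0.0306), Atp2a1 in BXH2 had 0.0601, and no other named call changed.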

Other observations

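The clock summary, the NK and clock counts of BXH6 and BXH10 and the choice of genes here were made only after the values were seen, and none was tested against an explanation.

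Clock genes placed most RI strains outside the range of both progenitors. Dbp had signals of 169 ± 38.4 in B6, 378 ± 35.0 in C3 and 174 ± 21.9 in F1 (SD, n = 2 each), but from 571 ± 94.4 in BXH7 to 2222 ± 148 in BXH8 among the RI strains, above both progenitors in 9 of 9, and its RI mean exceeded the midparent by a log2 value of 2.30. Arntl, which Nr1d1 and Nr1d2 repress, lay below both progenitors in 9 of 9 RI strains, with an RI mean of -1.65 relative to the midparent. Over 10 genes on the side of Dbp the median was 1.07 with 10 above 0, and over Arntl and Clock it was -1.02. The mean of the clock list per array was 8.87 to 9.21 in B6, C3 and F1, 9.18 on both BXH7 arrays and 9.46 to 10.13 on all other RI arrays. The labels give no hour of collection.

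The class II gene H2-Ea, in which C57BL/6J carries a known deletion, stayed below the filter with all its probe sets. On one of these the mean signal was 19.3 in B6 and 112 in C3, and it was 102 in BXH2, 127 in BXH6, 199 in BXH7 and 115 in BXH14, against at most 26.4 in the other RI strains. The other probe sets gave 31.2 in B6 and 40.8 in C3, and 6.65 and 19.7, and on both the same 4 strains overlapped the other RI strains. These 4 strains are those nearer C3 in H2-D1, H2-K1 and Glo1.

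In BXH6, 3 of 8 NK cell genes fell, and 6 adjusted over the list alone (adjusted p = 0.0897 with an estimated correlation). In BXH10, 3 of 15 clock genes rose, and 6 adjusted over the list alone (adjusted p = 0.188 with an estimated correlation).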
